A study of Mus musculus with 84 samples.

How the data were processed

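Messenger RNA abundance was measured by paired-end sequencing in 84 libraries, 7 tissues from each of 12 mice, and 3 tables gave blood work, body composition and organ weights per mouse. The groups were taken from the sample titles, which give genotype, diet, mouse number and tissue. In 6 titles the high-fat diet is spelled HDF, read as HFD. The labels give 20 weeks, without saying whether this is age or time on diet.

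The deposited count table holds whole-number fragment counts per Ensembl gene, 49671 genes in all, made per the file headers with featureCounts 1.5.1 on paired-end alignments over exons of a GRCm38 annotation, with no strand option. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with HISAT2 2.0.5 to GRCm38 and counted with featureCounts 1.5.0-p2, a version other than that in the file header. Without the strand option, reads of overlapping genes on opposite strands cannot be told apart. Without the option for reads that match several places, genes with near-identical copies are undercounted, so single values of such families are uncertain. The deposited phenotype tables hold other values, 1 per mouse, as the authors recorded them. Per the file headers these are U/L for both aminotransferases, mg/dL for cholesterol, glucose and triglyceride, uEq/L for free fatty acids and ng/ml for leptin, and no unit is named for weights, body composition and fasting glucose.

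Gene names and GRCm38 coordinates were taken from the reference tables, which named 49326 of the gene IDs and left 345 without a symbol. No library was left out. Each of the 84 libraries was closest in its counts to another of its own tissue, and no pair of replicates was as close as repeated counting of 1 library would be (chi-square per degree of freedom 2.77 to 628.04).

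Each tissue was fitted by itself with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (smallest count 10, smallest total count 15), libraries were scaled by TMM, and the quasi-likelihood test was run on a model with a mean for each of the 4 groups of 3 libraries, which share an estimate of the spread. The contrasts were genotype (mean of both ob/ob groups minus mean of both WT groups), HFD minus ND in WT mice, the same in ob/ob mice, and the interaction (the diet effect in ob/ob mice minus that in WT mice). Adjusted p values are Benjamini-Hochberg values within a tissue and contrast, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts relative to TMM-scaled library sizes. A gene with 0 counts in a group was given a lower bound, with 3 counts over the group as the floor, and for genes with 1 to 3 counts only the levels are given. Such bounds cover counting error only.

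The model, contrasts, 40 gene lists and the rule for naming genes were fixed before the data were examined. The rule takes genes past the threshold with a regular symbol, an average logCPM of at least 1 and no overlap between the libraries of both sides: the 4 highest and 4 lowest log2 fold changes per tissue for genotype, 3 and 3 for each diet contrast, and 2 and 2 for the interaction, where overlap was not considered. It also takes up to 4 members with the smallest p of each list, Lep, and Lepr in hypothalamus. For 3 libraries against 3, chance alone separates 10 percent of genes. Genes outside the rule, such as Hsf1, Cirbp, Rbm3, Mt2 and Nnt, and further list members, were chosen after their values were seen. Some genes that the rule takes are not reported here, and they stay in the counts. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 156 list and tissue pairs of a contrast, leaving out lists with under 5 tested members.

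Phenotypes were compared by exact two-sided permutation of the mean difference, with genotype permuted within diet and diet within genotype, adjusted over 18 measures. Genes called the same way in at least 4 tissues were set against 10000 random draws of as many called genes per tissue and direction. The gene fit was tested on simulated counts with 200 changed genes. For genotype, 44.8 to 91 percent of genes changed by 2-fold were recovered, depending on tissue. For diet in WT mice it was 10.4 to 80.6 percent at 2-fold and 62.1 to 98.5 percent at 4-fold, so smaller diet effects could be missed. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, the mouse number as a block, each mouse left out, an estimated correlation for the lists, and ranks or a log2 scale for phenotypes. Marker scores as covariates, leaving out 2 muscle libraries (a pair picked by eye, and the pair farthest from the median library), genotype on each diet alone, and the exact test of the difference of the diet effects on phenotypes were added after the data were seen.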

Results

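RNA was sequenced from 7 tissues of 12 mice: aorta, epididymal fat, heart, hippocampus, hypothalamus, liver and skeletal muscle. The mice were either wild type (WT) or ob/ob, a strain that is obese because a nonsense mutation in the leptin gene, Lep, leaves it without working leptin. Each genotype was kept on a normal diet (ND) or a high-fat diet (HFD), with 3 mice per genotype and diet and 20 weeks given in the labels. The 84 libraries thus form 28 groups of 3. Total gene counts ran from 10499528 to 17040790 per library, and 10 genes took between 6.24 and 40.2 percent of the counts of a library. Blood work, body composition and organ weights of the 12 mice were measured as well. Unless stated otherwise, ± after a log2 fold change is the standard error of the fit, ± after CPM (counts relative to the TMM-scaled library size) or a phenotype is the SD over 3 mice, and a gene is said to rise, fall or differ only past an adjusted p of 0.05 by edgeR's quasi-likelihood test.

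**Figure D1:**
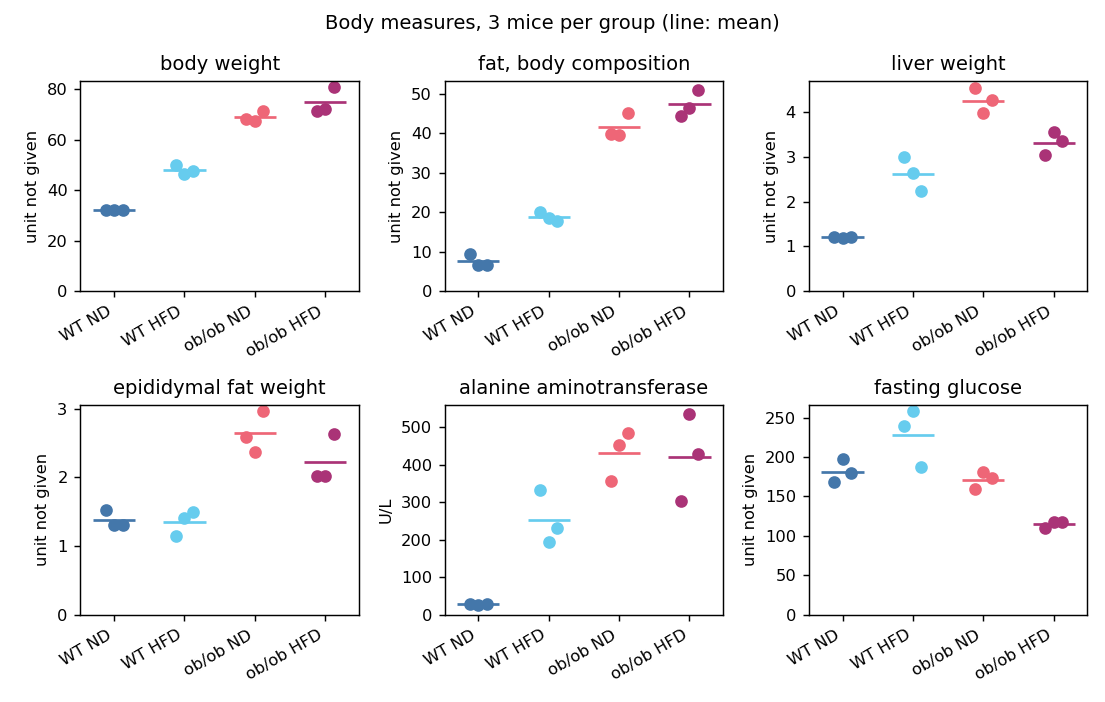
Body weight, body fat, liver weight, epididymal fat weight, alanine aminotransferase (U/L) and fasting glucose in each of the 12 mice; points are mice, lines are means of 3 and units are not given except where stated. Mean body weight runs from 32.1 in WT mice on ND to 74.8 in ob/ob mice on HFD, while mean liver weight is 4.26 in ob/ob mice on ND and 3.32 on HFD.

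The ob/ob mice were heavier and fatter than WT mice, and their livers and fat depots weighed more. Body weight was 32.1 ± 0.153 in WT mice on ND, 48.1 ± 1.88 in WT mice on HFD, 68.9 ± 2.10 in ob/ob mice on ND and 74.8 ± 5.25 in ob/ob mice on HFD, in a unit the table does not name. Body fat in the same order was 7.56 ± 1.60, 18.9 ± 1.10, 41.5 ± 3.20 and 47.4 ± 3.38, and lean mass was 22.1 ± 1.47, 25.99 ± 1.18, 22.6 ± 1.12 and 23.1 ± 1.42. The liver weighed 1.20 ± 0.00721, 2.63 ± 0.390, 4.26 ± 0.270 and 3.32 ± 0.268, and the brain was lighter in ob/ob mice, at 0.365 ± 0.0103 against 0.478 ± 0.00321 on ND. Alanine aminotransferase, a blood enzyme that rises with liver damage, was 28.0 ± 1.73 U/L in WT mice on ND, 253 ± 72.2 on HFD, and 431 ± 65.9 and 421 ± 116 U/L in ob/ob mice on the respective diets.

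For genotype, 11 of 18 measures passed an adjusted p of 0.05 in an exact two-sided permutation test with labels permuted within diet (6 mice against 6). Body weight, body fat, brain and liver weight, mesenteric, epididymal and retroperitoneal fat and aspartate aminotransferase each reached exact permutation p = 0.005, the smallest this design allows, with adjusted p = 0.0112. Alanine aminotransferase (exact permutation p = 0.01, adjusted p = 0.02) and total cholesterol (270.5 against 174 mg/dL, adjusted p = 0.0409 by the same exact test) were also higher in ob/ob mice, and fasting glucose was lower (143 against 205, adjusted p = 0.0409 by the same exact test). The call for cholesterol was lost without WT mouse 2 on ND (difference 95.83 mg/dL), WT mouse 3 on HFD (91.17) or ob/ob mouse 1 or 3 on HFD (92.08 and 78.08). That for fasting glucose was lost without WT mouse 2 on ND (-58.17), ob/ob mouse 1 on ND (-59.17) or ob/ob mouse 1 or 3 on HFD (-60.75 and -62.5). For diet within a genotype, 3 mice against 3 cannot reach an exact p below 0.1, and no measure passed. Mean liver weight was higher on HFD in WT mice and lower in ob/ob mice (exact permutation p = 0.005 for the difference of the diet effects, adjusted p = 0.09). Leptin was listed at 0 in all WT mice on ND and all ob/ob mice, and at 708 ± 124 in WT mice on HFD, under a column name that gives ng/ml; a level of 0 in WT mice on ND and the size on HFD leave the scale of that column open.

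Lep (ENSMUSG00000059201; GRCm38 chromosome 6, 29060220 to 29073877) was higher in ob/ob mice in epididymal fat, aorta and muscle as the mean over both diets. In epididymal fat the 6 ob/ob libraries held 2336 to 4991 CPM and the 6 WT libraries 467 to 2153 CPM (log2 fold change 1.24 ± 0.33, adjusted p = 0.0128). The aorta samples held 729.6 to 1845 CPM in ob/ob mice and 9.52 to 160.3 CPM in WT mice (5.07 ± 0.24, adjusted p = 8.1e-08), and skeletal muscle 508 to 3478 against 12.4 to 1137 CPM (3.44 ± 0.60, adjusted p = 0.00242). On each diet alone it passed in aorta on both and in epididymal fat on neither (adjusted p = 0.0651 and 0.066). In muscle it passed on ND (5.69 ± 0.95, adjusted p = 0.00326 by edgeR) and not on HFD (1.19 ± 0.79, 0.403). Muscle samples also differed in the adipocyte transcript Adipoq, and aorta samples held it in every group, both given below. In liver Lep stayed near the detection limit (1.41 ± 1.15, adjusted p = 0.348), and it had too few counts to be tested in heart, hippocampus and hypothalamus. Gene counts do not show the nonsense mutation, so they do not check the genotype labels. The leptin receptor gene, Lepr, did not pass in hypothalamus (0.17 ± 0.18, adjusted p = 0.575). It was higher in heart (0.55 ± 0.19, adjusted p = 0.0405) and liver (0.64 ± 0.23, 0.0416). Both calls are fragile, lost without any 1 of 7 libraries in heart (adjusted p up to 0.13 by edgeR) and of 9 in liver (up to 0.104). On ND alone neither passed (0.28 and 0.11), and on HFD both did (0.82 and 1.16).

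Transcriptomes of all 7 tissues differed by genotype, comparing the mean of both ob/ob groups with that of both WT groups (6 libraries against 6). The count of genes past the threshold was 7506 of 15452 tested in skeletal muscle (4292 higher and 3214 lower in ob/ob mice) and 5844 of 14761 in aorta (2991 and 2853). It was 5664 of 13246 in liver (2928 and 2736), 5621 of 15676 in epididymal fat (3232 and 2389) and 4119 of 13673 in heart (1993 and 2126). The brain regions had fewer, 2565 of 16537 in hypothalamus (1183 and 1382) and 2272 of 16361 in hippocampus (1051 and 1221). Changes of at least 2-fold were 3382 in muscle, 1362 in epididymal fat, 1057 in liver, 1053 in aorta, 319 in heart, 137 in hypothalamus and 135 in hippocampus. Tested on ND and on HFD alone (3 mice against 3, an alternative added after the data were seen), genotype gave 6950 and 3 in skeletal muscle, 7558 and 2752 in epididymal fat, 4816 and 2445 in liver, 4685 and 2389 in aorta. It gave 1742 and 2349 in heart, 877 and 353 in hypothalamus and 569 and 255 in hippocampus. In lists, whose members are counted once per list, the members called for the mean were 202, 180, 199, 65, 109, 259 and 250 in aorta, epididymal fat, heart, hippocampus, hypothalamus, liver and muscle. Those passing the same way were 145, 144, 113, 22, 39, 217 and 221 on ND alone and 96, 61, 125, 20, 40, 116 and 0 on HFD alone, and 4, 56, 5, 0, 0, 18 and 3 had the opposite sign on HFD; on ND it was 11 in epididymal fat, 7 in liver and 1 in heart. The hypothalamus count was 4511 without the first WT mouse on ND, 1688 without the second WT mouse on HFD and 1601 without the first ob/ob mouse on HFD. The hippocampus count was 1467 and 1407 without WT mouse 1 or 2 on ND, 1465 without WT mouse 2 on HFD and 1426 without ob/ob mouse 1 on HFD. Of the 156 tests of a gene list in a tissue, 71 passed with the preset correlation of 0.01 and 0 with an estimated correlation. Other splits of the same mice called a median of 61 lists and at most 87 with the preset correlation, so its p values do not set a list apart here, and each list is described by the calls of its measured members.

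**Figure D2:**
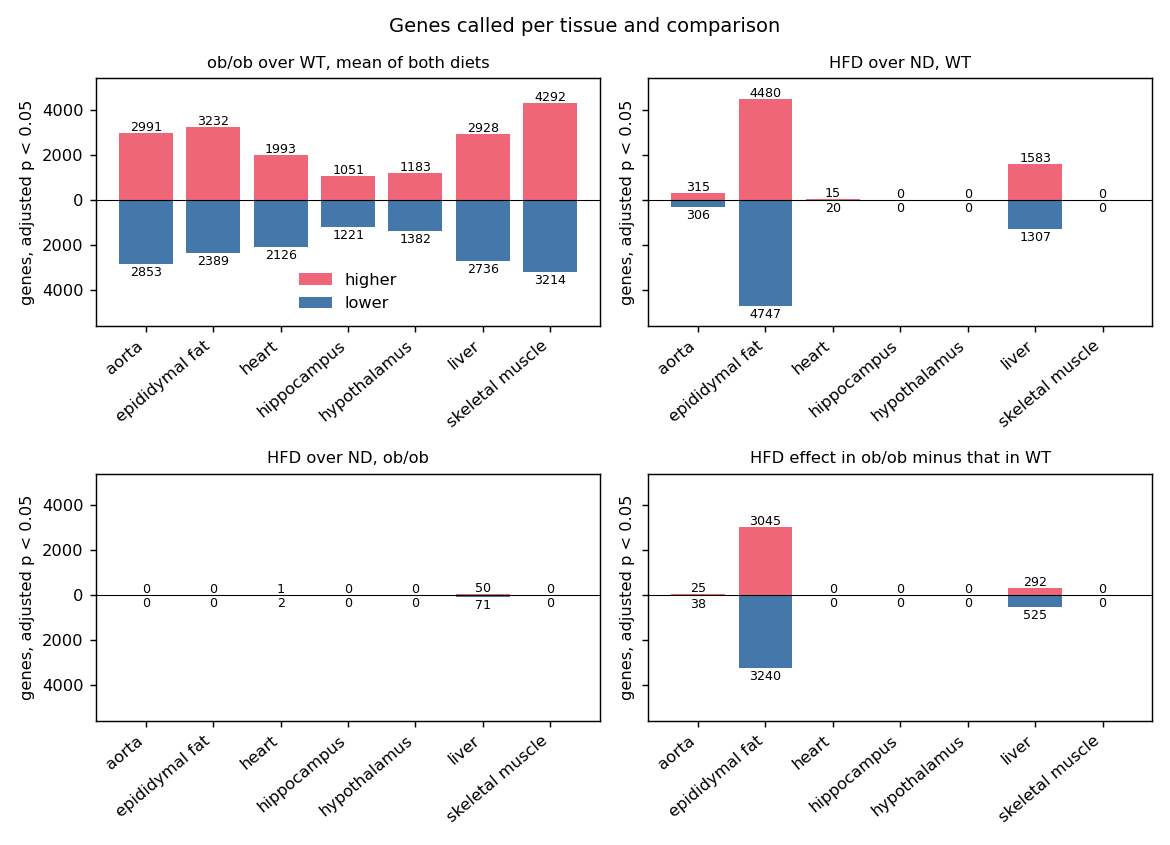
Genes past an adjusted p of 0.05 per tissue and comparison, higher (above 0) and lower (below 0) in the first-named group; the vertical axis is the number of genes. Genotype counts run from 2272 in hippocampus to 7506 in skeletal muscle, while HFD in WT mice reached 9227 in epididymal fat and HFD in ob/ob mice at most 121, in liver.

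In liver, male-biased transcripts were lower in ob/ob mice and most female-biased transcripts higher. Of the male-biased list, 0 of 19 members rose, 19 fell and 0 did not pass (0 and 19 adjusted over the list alone, adjusted p = 4.36e-20 by camera, adjusted p = 0.216 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase of the acidic bile acid pathway, had a log2 fold change of -3.61 ± 0.20, Elovl3, a fatty acid elongase, had -4.003 ± 0.23, and Cyp2u1 had -1.98 ± 0.14. The naming rule gave major urinary protein genes, secreted pheromone carriers, among those that fell: Mup11 (ENSMUSG00000073834; chromosome 4, 60658466 to 60662411) went from 1172 ± 87 CPM in WT to 6.19 ± 8.95 CPM in ob/ob mice on ND (log2 fold change -7.57 on ND and -9.19 ± 1.09 as the mean over both diets), with Mup12 at -9.17 ± 1.06 and Mup1 at -8.29 ± 1.02. WT mice on HFD differed greatly in these, with Mup11 at 1185 ± 1810, Mup12 at 127 ± 191 and Mup1 at 95.95 ± 143 CPM. Mup16 held 2 counts in ob/ob mice on HFD, and its mean fell from 55.7 ± 25.8 to 0.0958 ± 0.0830 CPM on ND. Mup genes are near-identical copies, so how reads were divided among them is uncertain. In the female-biased list, 12 of 17 members rose, 1 fell and 4 did not pass (12 and 1 adjusted over the list alone, adjusted p = 3.27e-07 by camera, adjusted p = 0.125 with an estimated correlation). Sult1e1, an oestrogen sulfotransferase, had 6.47 ± 0.53, the cytochrome P450 gene Cyp2a4 4.58 ± 0.42 and Ntrk2, a neurotrophin receptor, 3.64 ± 0.27. Ephb2, an ephrin receptor with 1 count in WT mice on ND, stood at 32.4 ± 7.35 CPM in ob/ob mice on ND. Sprr1a and Shc2 had 0 counts in all 3 WT livers on ND, which makes the ob/ob mean on ND at least 148-fold higher for Sprr1a and at least 59.2-fold higher for Shc2, taking 3 counts over the group as the floor.

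In the ob/ob liver most fatty acid synthesis and lipid droplet genes were higher and most heat shock genes lower, as the mean over both diets. For fatty acid synthesis, 13 of 17 members rose, 1 fell and 3 did not pass (13 and 1 adjusted over the list alone, adjusted p = 0.000246 by camera, adjusted p = 0.373 with an estimated correlation). Srebf1, a transcription factor of lipid synthesis, stood at 1.53 ± 0.17, the desaturase gene Scd2 at 2.13 ± 0.26, and Mlxipl, which encodes the glucose-responsive factor ChREBP, at -0.62 ± 0.06. In the lipid droplet list, 10 of 16 members rose, 1 fell and 5 did not pass (10 and 3 adjusted over the list alone, adjusted p = 0.000228 by camera, adjusted p = 0.373 with an estimated correlation). Examples were the droplet proteins Cidec (2.18 ± 0.17), Plin4 (1.68 ± 0.19) and Cidea (3.92 ± 0.47). On ND alone 12 of the 14 called synthesis genes and 10 of the 11 droplet genes passed the same way, and on HFD alone 2 and 3. In fatty acid oxidation 4 of 24 members rose, 8 fell and 12 did not pass (4 and 8 adjusted over the list alone, adjusted p = 0.452 by camera, adjusted p = 0.904 with an estimated correlation). Cytosolic heat shock genes mostly fell: 1 of 14 members rose, 11 fell and 2 did not pass (1 and 12 adjusted over the list alone, adjusted p = 3.15e-12 by camera, adjusted p = 0.152 with an estimated correlation). The chaperone Hsph1 stood at -2.49 ± 0.13 and the co-chaperones Fkbp4 at -0.92 ± 0.06 and Stip1 at -0.94 ± 0.07. Of the unfolded protein and integrated stress response list, 3 of 20 members rose, 12 fell and 5 did not pass (3 and 12 adjusted over the list alone, adjusted p = 1.25e-10 by camera, adjusted p = 0.152 with an estimated correlation). Its lowest p values belonged to chaperones of the endoplasmic reticulum, Creld2 (-2.16 ± 0.12), Hyou1 (-1.92 ± 0.11) and Hspa5 (-1.23 ± 0.08). Among bile acid genes 2 of 15 members rose, 10 fell and 3 did not pass (2 and 10 adjusted over the list alone, adjusted p = 5.95e-05 by camera, adjusted p = 0.324 with an estimated correlation). Examples were Nr0b2, the repressor SHP (-2.06 ± 0.18), and the bile salt exporter Abcb11 (-0.89 ± 0.11). Of the interferon response genes 1 of 21 members rose, 15 fell and 5 did not pass (1 and 16 adjusted over the list alone, adjusted p = 0.000136 by camera, adjusted p = 0.627 with an estimated correlation). Rtp4 stood at -1.13 ± 0.11. Of these 16 calls 15 passed the same way on HFD alone and 5 on ND alone, where 5 had the opposite sign. Macrophage markers were higher where they passed, 10 of 25 members rose, 0 fell and 15 did not pass (10 and 0 adjusted over the list alone, adjusted p = 0.0011 by camera, adjusted p = 0.646 with an estimated correlation). The elastase Mmp12 stood at 3.32 ± 0.27 and Gpnmb, a marker of lipid-laden macrophages, at 3.32 ± 0.57. Of the hepatocyte markers, the main cell type, 2 of 16 members rose, 9 fell and 5 did not pass (2 and 9 adjusted over the list alone, adjusted p = 0.0309 by camera, adjusted p = 0.627 with an estimated correlation), and the called ones had a median log2 fold change of -0.59 on ND and -0.17 on HFD. Of the endothelial markers 5 of 14 members rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone, adjusted p = 0.179 by camera, adjusted p = 0.744 with an estimated correlation), and of the blood haemoglobin list 6 of 8 members rose, 2 fell and 0 did not pass (6 and 2 adjusted over the list alone, adjusted p = 0.59 by camera, adjusted p = 0.897 with an estimated correlation).

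In epididymal fat of ob/ob mice, cell division and most macrophage genes were higher as the mean over both diets, and the beta-adrenergic receptor of adipocytes was lower. For the cell cycle, 20 of 20 members rose, 0 fell and 0 did not pass (20 and 0 adjusted over the list alone, adjusted p = 1.42e-18 by camera, adjusted p = 0.219 with an estimated correlation). The spindle protein Tpx2 stood at 1.29 ± 0.12 and cyclin Ccnb2 at 1.48 ± 0.14. Of the macrophage markers, 15 of 24 members rose, 2 fell and 7 did not pass (15 and 2 adjusted over the list alone, adjusted p = 5.94e-12 by camera, adjusted p = 0.373 with an estimated correlation). Examples were Trem2, a lipid receptor of fat-associated macrophages (2.42 ± 0.12), Mpeg1 (1.94 ± 0.13) and the F4/80 gene Adgre1 (1.20 ± 0.08). On ND alone all 17 called macrophage markers and all 20 cell cycle genes passed in the same direction. On HFD alone 15 of the 17 macrophage markers had the opposite sign (3 past the threshold), and so did 13 of the 20 cell cycle genes (0 past it). Trem2 stood at 10.2 ± 0.696 and 379.6 ± 74.2 CPM in WT and ob/ob mice on ND and at 656 ± 108 and 506 ± 67.5 CPM on HFD, and Adgre1 on HFD at 842 ± 10.4 and 536 ± 57.0 CPM. Itgad, an integrin of foam cells, went from 0.430 ± 0.481 to 213 ± 79.4 CPM on ND (log2 fold change 8.96 on ND, 2.15 on HFD and 5.56 ± 0.28 as the mean over both diets), Gpr50 had 4.88 ± 0.42 and Pex5l had 4.86 ± 0.41. Ppp1r3a, a glycogen-targeting phosphatase subunit with 2 counts in WT mice on ND, stood at 35.05 ± 20.8 CPM in ob/ob mice on ND. Adrb3, the beta-3 adrenergic receptor (ENSMUSG00000031489; chromosome 8, 27225776 to 27250616), fell from 584 ± 100 to 4.30 ± 1.78 CPM on ND (-7.07 on ND, -1.79 on HFD and -4.43 ± 0.31 as the mean over both diets), and so did Sult1e1 (-4.55 ± 0.44), the lectin receptor Cd209a (-4.03 ± 0.37) and Lgals7 (-3.83 ± 0.44). For cholesterol synthesis and uptake, 14 of 21 members rose, 1 fell and 6 did not pass (15 and 1 adjusted over the list alone, adjusted p = 7.26e-07 by camera, adjusted p = 0.165 with an estimated correlation). The reductase Dhcr7 stood at 1.24 ± 0.11. All 15 of these calls passed on ND alone, and on HFD alone 7 did, with 3 of opposite sign (1 past the threshold). Interferon genes were lower, 0 of 21 members rose, 11 fell and 10 did not pass (0 and 11 adjusted over the list alone, adjusted p = 0.000135 by camera, adjusted p = 0.614 with an estimated correlation), Ifitm3 at -0.84 ± 0.08 among them. The adipocyte transcript Adipoq, which encodes adiponectin, stood at 6330 ± 748 CPM in WT mice on ND and between 656 and 1177 CPM in the other groups. Of the white adipocyte list, 2 of 20 members rose, 4 fell and 14 did not pass (2 and 4 adjusted over the list alone, adjusted p = 0.265 by camera, adjusted p = 0.897 with an estimated correlation). The called ones had a median of -3.25 on ND and 1.03 on HFD, where 3 had the opposite sign (1 past the threshold).

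As the mean over both diets, skeletal muscle of ob/ob mice had more macrophage, matrix and adipocyte transcripts and less of the respiratory chain. On HFD alone 3 genes passed for genotype, and 0 of the called macrophage, matrix, adipocyte and respiratory chain genes did. Of the macrophage markers, 23 of 24 members rose, 0 fell and 1 did not pass (23 and 0 adjusted over the list alone, adjusted p = 1.62e-10 by camera, adjusted p = 0.519 with an estimated correlation). Lgals3 stood at 3.21 ± 0.44 and Trem2 at 3.05 ± 0.48. Extracellular matrix genes followed, 22 of 27 members rose, 0 fell and 5 did not pass (23 and 0 adjusted over the list alone, adjusted p = 5.09e-07 by camera, adjusted p = 0.614 with an estimated correlation). Examples were the crosslinking enzyme Lox (2.79 ± 0.33) and the basement membrane collagen Col4a2 (2.45 ± 0.39). Oxidative phosphorylation genes fell, 0 of 31 members rose, 29 fell and 2 did not pass (0 and 31 adjusted over the list alone, adjusted p = 1.18e-08 by camera, adjusted p = 0.627 with an estimated correlation). Examples were Uqcrc1 of complex III (-1.06 ± 0.20) and Ndufs1 of complex I (-1.13 ± 0.23). In the glucocorticoid-responsive list, 8 of 20 members rose, 3 fell and 9 did not pass (9 and 3 adjusted over the list alone, adjusted p = 0.0277 by camera, adjusted p = 0.255 with an estimated correlation). The glucocorticoid receptor co-chaperone Fkbp5 stood at 1.35 ± 0.13, the metallothionein Mt2 at 2.47 ± 0.25 and Lcn2, an iron-binding protein of inflammation, at 3.65 ± 0.36. Further rises were Pex5l (4.90 ± 0.51), Plppr4 (4.63 ± 0.49), the carbonic anhydrase Car12 (3.92 ± 0.52) and the chitinase-like macrophage gene Chil3, which held 2 counts in WT mice on ND and 12.3 ± 11.9 CPM in ob/ob mice on HFD. The polyamine enzyme genes Amd1 (-3.72 ± 0.74) and Amd2 (-3.87 ± 0.68), which share reads and are uncertain singly, fell together with cardiac actin, Actc1 (-3.65 ± 0.56), and the calcium channel subunit Cacna2d4 (-3.60 ± 0.45).

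Adipocyte and blood transcripts in the muscle samples differed as well. Of the white adipocyte list, 13 of 20 members rose, 2 fell and 5 did not pass (15 and 2 adjusted over the list alone, adjusted p = 0.00156 by camera, adjusted p = 0.669 with an estimated correlation). Examples were the natriuretic peptide receptor Npr3 (2.82 ± 0.56) and the lipase Pnpla2 (1.33 ± 0.31). Adipoq was 137 ± 140.0 CPM in WT mice on ND and 1305 ± 317 in ob/ob mice on ND, while the fast myosin Myh4 went from 36540 ± 16300 to 6226 ± 5930 CPM. On HFD Adipoq was 1043 ± 303 CPM in WT and 1323 ± 910.0 in ob/ob mice, and Myh4 21980 ± 4320 and 9132 ± 13900 CPM. The ob/ob mice on HFD differed among themselves, with Adipoq at 334, 2124 and 1511 CPM and Myh4 at 25210, 533 and 1654 CPM in mice 1, 2 and 3. Of the blood haemoglobin list 7 of 9 members rose, 2 fell and 0 did not pass (7 and 2 adjusted over the list alone, adjusted p = 0.105 by camera, adjusted p = 0.765 with an estimated correlation). Of the fast fibre list, 0 of 15 members rose, 4 fell and 11 did not pass (0 and 0 adjusted over the list alone, adjusted p = 0.000319 by camera, adjusted p = 0.637 with an estimated correlation). With the adipocyte score of each library as a covariate, an alternative added after the data were seen, the genotype count was 202 instead of 7506. Of 23 called values of genes named here or below, 12 kept their call with it, Lox (1.81) and Lep (1.75) among them. It ended the calls of Trem2 (log2 fold change 1.62, adjusted p = 0.105 by edgeR), Lgals3 (2.09, 0.0608), Col4a2 (1.31, 0.081), Uqcrc1 (-1.03, 0.0733, its fold change little moved), Ndufs1 (-0.85, 0.122), Car12 (2.84, 0.0547), Chil3 (adjusted p = 0.0591), Amd1 (-2.79, 0.0503) and Pnpla2 (0.46, 0.314).

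The aorta samples of ob/ob mice showed lower respiratory chain, fatty acid oxidation and interferon transcripts, and most matrix genes and macrophage markers that passed were higher. For oxidative phosphorylation, 0 of 31 members rose, 20 fell and 11 did not pass (0 and 21 adjusted over the list alone, adjusted p = 9.39e-08 by camera, adjusted p = 0.614 with an estimated correlation). Ndufb3 of complex I stood at -0.77 ± 0.13. In the fatty acid oxidation list, 2 of 24 members rose, 14 fell and 8 did not pass (3 and 15 adjusted over the list alone, adjusted p = 0.0016 by camera, adjusted p = 0.637 with an estimated correlation). An example was the peroxisomal enzyme Ehhadh (-1.28 ± 0.19). Interferon response genes were lower, 0 of 21 members rose, 15 fell and 6 did not pass (0 and 15 adjusted over the list alone, adjusted p = 1.32e-05 by camera, adjusted p = 0.614 with an estimated correlation). Bst2 stood at -0.74 ± 0.11. Matrix genes were mostly higher where they passed, 11 of 27 members rose, 1 fell and 15 did not pass (11 and 1 adjusted over the list alone, adjusted p = 0.000427 by camera, adjusted p = 0.627 with an estimated correlation). Lox stood at 1.83 ± 0.14 and thrombospondin, Thbs1, at 2.27 ± 0.24. Among macrophage markers 10 of 24 members rose, 0 fell and 14 did not pass (10 and 0 adjusted over the list alone, adjusted p = 1.32e-05 by camera, adjusted p = 0.637 with an estimated correlation). Examples were the proton pump subunit Atp6v0d2 (4.003 ± 0.31) and Mmp12 (3.07 ± 0.24). By the naming rule, Tph2, the serotonin-synthesising enzyme of neurons (5.35 ± 0.29), Lep and the oxytocin receptor Oxtr (4.97 ± 0.39) rose. The choline transporter Slc5a7 had 0 counts in WT mice on ND, and its ob/ob mean on ND was at least 169-fold higher on the floor of 3 counts. Downward, Retnla, a marker of alternatively activated macrophages, had -2.70 ± 0.27, and the lectin receptors Cd209a (-2.71 ± 0.36), Cd209d (-2.86 ± 0.42) and Cd209g (-2.53 ± 0.53), related copies whose single values are uncertain, fell as well. Ucp1, the uncoupling protein of brown fat, was 10020 ± 1930 CPM in WT and 4711 ± 1150 CPM in ob/ob mice on ND, lower along with the respiratory chain and fatty acid oxidation lists.

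In the heart of ob/ob mice most interferon, antigen presentation and matrix genes that passed were lower, and most clock genes that passed higher. In the interferon list, 0 of 21 members rose, 18 fell and 3 did not pass (0 and 20 adjusted over the list alone, adjusted p = 8.32e-15 by camera, adjusted p = 0.159 with an estimated correlation). Bst2 stood at -0.99 ± 0.09 and the guanylate-binding protein Gbp2 at -1.08 ± 0.10. Of the lymphocyte and antigen presentation list, 0 of 10 members rose, 6 fell and 4 did not pass (0 and 6 adjusted over the list alone, adjusted p = 4.79e-05 by camera, adjusted p = 0.374 with an estimated correlation), the class II genes H2-Ab1 (-0.84 ± 0.11) and H2-Eb1 (-0.89 ± 0.12) among them. Of the matrix genes 1 of 27 members rose, 14 fell and 12 did not pass (2 and 14 adjusted over the list alone, adjusted p = 1.85e-06 by camera, adjusted p = 0.581 with an estimated correlation). Col6a3 stood at -1.24 ± 0.11 and Col3a1 at -1.33 ± 0.14. Macrophage markers fell more often than they rose, 2 of 23 members rose, 9 fell and 12 did not pass (2 and 12 adjusted over the list alone, adjusted p = 0.00381 by camera, adjusted p = 0.671 with an estimated correlation). For the circadian clock, 13 of 19 members rose, 1 fell and 5 did not pass (13 and 1 adjusted over the list alone, adjusted p = 1.19e-10 by camera, adjusted p = 0.0554 with an estimated correlation). The period gene Per2 had 1.29 ± 0.09, the transcription factor Tef 0.78 ± 0.07 and the repressor Ciart 1.62 ± 0.16. Myostatin, Mstn, a brake on muscle growth, rose as well (2.67 ± 0.40). The genes of the naming rule were Trp63 (3.40 ± 0.33), Fam222a (2.40 ± 0.23) and the potassium channel Kcnk1 (2.29 ± 0.25) upward, and the Fc receptor-like gene Fcrls (-1.92 ± 0.16), the chemokine Cxcl9 (-1.62 ± 0.17), B3galt2 (-1.62 ± 0.19) and Apol10b (-1.56 ± 0.24) downward. Snhg11 held 3 counts in WT mice on ND and stood at 6.30 ± 2.21 CPM in ob/ob mice on ND.

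In the hypothalamus, the appetite peptides Npy and Agrp were higher in ob/ob mice and Pomc and Cartpt lower. Most myelin, microglia and heat shock transcripts that passed were lower, and clock and glucocorticoid-responsive transcripts higher. Of the myelin list, 0 of 18 members rose, 12 fell and 6 did not pass (1 and 14 adjusted over the list alone, adjusted p = 1.08e-12 by camera, adjusted p = 0.165 with an estimated correlation). Ugt8a, an enzyme of myelin lipid synthesis, stood at -1.01 ± 0.07 and Fa2h at -0.74 ± 0.07. Microglia markers that passed all fell, 0 of 20 members rose, 8 fell and 12 did not pass (0 and 13 adjusted over the list alone, adjusted p = 5.52e-10 by camera, adjusted p = 0.139 with an estimated correlation). Examples were Fcrls (-1.32 ± 0.11) and Olfml3 (-1.004 ± 0.09). In the clock list 13 of 19 members rose, 0 fell and 6 did not pass (14 and 1 adjusted over the list alone, adjusted p = 1.94e-12 by camera, adjusted p = 0.0554 with an estimated correlation). Among them were the cryptochromes Cry1 (1.03 ± 0.06) and Cry2 (0.63 ± 0.07). Of the glucocorticoid-responsive list, 9 of 20 members rose, 0 fell and 11 did not pass (11 and 0 adjusted over the list alone, adjusted p = 5.92e-07 by camera, adjusted p = 0.21 with an estimated correlation). Fkbp5 stood at 1.004 ± 0.08. Heat shock genes that passed fell, 0 of 15 members rose, 10 fell and 5 did not pass (0 and 12 adjusted over the list alone, adjusted p = 1.05e-10 by camera, adjusted p = 0.139 with an estimated correlation). In the unfolded protein and integrated stress response list 0 of 20 members rose, 10 fell and 10 did not pass (0 and 11 adjusted over the list alone, adjusted p = 3.13e-06 by camera, adjusted p = 0.324 with an estimated correlation). Wdfy1, an endosomal adaptor protein, had 2.10 ± 0.06, the insulin-responsive glucose transporter Slc2a4 1.73 ± 0.13, Hmgb2 1.61 ± 0.12 and Mid1 1.47 ± 0.24, while Pkd2l1, a channel of neurons that contact cerebrospinal fluid, had -2.08 ± 0.31 and the peptidase Klk6 -1.28 ± 0.16. The list of feeding neuropeptides and their receptors was not called (adjusted p = 0.265 by camera): 2 of 20 members rose, 4 fell and 14 did not pass (3 and 6 adjusted over the list alone). The appetite-stimulating peptides of the arcuate nucleus rose, Npy by 1.02 ± 0.14, adjusted p = 0.000816 and Agrp by 1.40 ± 0.21, adjusted p = 0.00133. The appetite-suppressing precursors fell, Pomc at -1.54 ± 0.33, adjusted p = 0.00865 and Cartpt at -0.84 ± 0.20, adjusted p = 0.0128, by edgeR.

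In the hippocampus, microglia, heat shock and unfolded protein genes that passed were lower in ob/ob mice. Microglia markers gave 12 lower of 20 (14 adjusted over the list alone, adjusted p = 4.01e-12 by camera, adjusted p = 0.21 with an estimated correlation). Olfml3 stood at -1.15 ± 0.11. Heat shock genes gave 5 lower of 15 (7 adjusted over the list alone, adjusted p = 9.14e-07 by camera, adjusted p = 0.0554 with an estimated correlation). The co-chaperone Chordc1 stood at -1.19 ± 0.12 and Hsph1 at -0.68 ± 0.06. In the unfolded protein list 0 of 19 members rose, 9 fell and 10 did not pass (1 and 12 adjusted over the list alone, adjusted p = 4.62e-07 by camera, adjusted p = 0.0849 with an estimated correlation), Sdf2l1 at -0.82 ± 0.11 among them, and in the clock list 7 of 19 members rose, 1 fell and 11 did not pass (8 and 1 adjusted over the list alone, adjusted p = 0.000146 by camera, adjusted p = 0.207 with an estimated correlation). An example was Cry1 (0.88 ± 0.09). Wdfy1 again rose (2.13 ± 0.08), as did the ligand Wnt10b (2.74 ± 0.47), the tachykinin Tac2 (1.96 ± 0.51) and Lrrc29 (1.53 ± 0.22), whereas Zbtb40 (-1.22 ± 0.16) and the histone gene Hist1h2be (-1.28 ± 0.18) fell. Panct2 also fell (-1.23 ± 0.19), an antisense transcript whose reads cannot be told from those of its partner without strand. Tac2 lost its call without any 1 of 5 libraries (adjusted p up to 0.0742 by edgeR). The choroid plexus transcript Ttr ran from 45.7 to 5778 CPM within the WT mice on ND.

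Many genes moved the same way in several tissues of ob/ob mice. Among 11350 genes tested in all 7 tissues, 1671 were called in the same direction in at least 4 tissues (937 higher and 734 lower), against a mean of 374 and a highest value of 445 in 10000 random draws (permutation p = 1e-04, the smallest the draws can give). All 7 tissues shared 74 genes, 29 higher and 45 lower. The tissues come from the same 12 mice, so these counts describe these animals. Of the genes higher in all 7, chosen for the text after their values were seen, Wdfy1 (ENSMUSG00000073643; chromosome 1, 79702262 to 79776143) had a mean log2 fold change of 2.04 (SD over the 7 tissues 0.22), Mid1 1.46 (SD 0.39) and Mt2 1.25 (SD 0.96). The cold-inducible RNA-binding protein genes Cirbp and Rbm3 had means of 1.02 (SD 0.24) and 0.95 (SD 0.25), and the clock gene Cry2 0.66 (SD 0.24). Lower in all 7 were Hsph1 at -1.02 (SD 0.67), Chordc1 at -1.02 (SD 0.40) and the heat shock transcription factor Hsf1 at -0.49 (SD 0.23). Hippocampus and hypothalamus shared 925 called genes, against 308 for independent lists, and all 925 had the same direction. Between heart and skeletal muscle 57.1 percent of 1784 shared calls did.

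**Figure D3:**
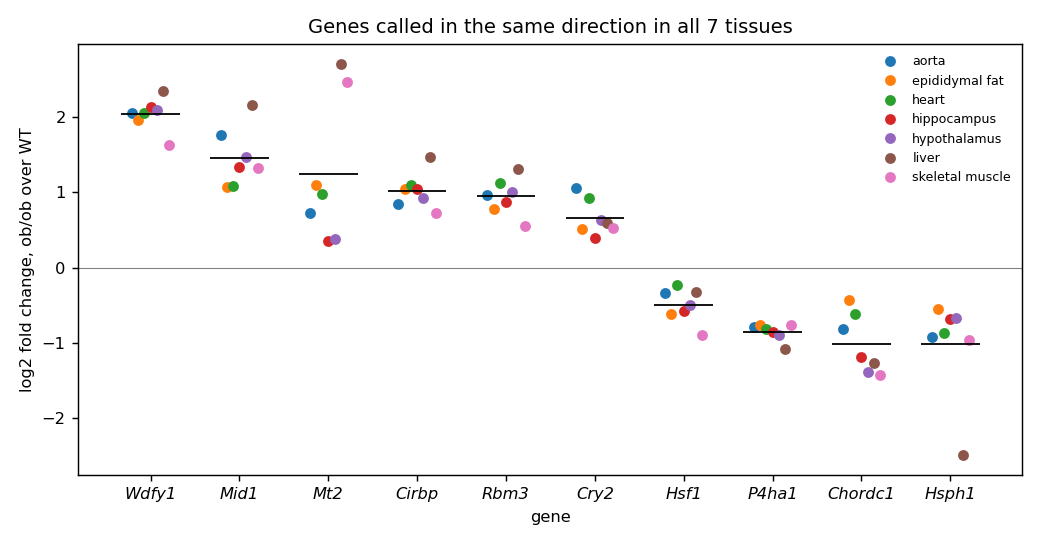
Log2 fold change (ob/ob over WT, mean of both diets) of 10 genes called in the same direction in all 7 tissues; each point is a tissue and the bar is the mean over the 7. Wdfy1 lies between 1.63 and 2.34 in every tissue, and Chordc1 and Hsph1 lie below 0 in each.

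On HFD the epididymal fat of WT mice differed, with 9227 of 15676 genes called (4480 higher and 4747 lower, 3 mice against 3). Macrophage markers rose, 21 of 24 members rose, 1 fell and 2 did not pass (21 and 1 adjusted over the list alone, adjusted p = 3.09e-22 by camera, adjusted p = 0.404 with an estimated correlation). Trem2 stood at 5.999 ± 0.21 and Adgre1 at 3.69 ± 0.13. Cell cycle genes rose as well, 20 of 20 members rose, 0 fell and 0 did not pass (20 and 0 adjusted over the list alone, adjusted p = 3.75e-16 by camera, adjusted p = 0.414 with an estimated correlation). White adipocyte genes fell, 0 of 20 members rose, 17 fell and 3 did not pass (0 and 18 adjusted over the list alone, adjusted p = 1.14e-08 by camera, adjusted p = 0.502 with an estimated correlation). Adrb3 stood at -4.76 ± 0.43, the glucose transporter Slc2a4 at -3.20 ± 0.36 and adipsin, Cfd, going from 5931 ± 1070 to 46.5 ± 39.0 CPM (-6.99 ± 0.67). In oxidative phosphorylation, 0 of 31 members rose, 28 fell and 3 did not pass (0 and 28 adjusted over the list alone, adjusted p = 4.27e-06 by camera, adjusted p = 0.502 with an estimated correlation), in fatty acid synthesis 0 of 17 members rose, 14 fell and 3 did not pass (0 and 14 adjusted over the list alone, adjusted p = 0.000344 by camera, adjusted p = 0.63 with an estimated correlation), and in the endothelial list 0 of 14 members rose, 14 fell and 0 did not pass (0 and 14 adjusted over the list alone, adjusted p = 0.00245 by camera, adjusted p = 0.689 with an estimated correlation). Osteopontin, Spp1, made by activated macrophages, went from 1.06 ± 0.913 to 1656 ± 1800 CPM (10.61 ± 1.44), and Retnla from 1004 ± 182 to 7.03 ± 6.74 CPM (-7.15 ± 0.95). Hmga2 and St18, with 0 counts on ND, were at least 141-fold and at least 105-fold higher on HFD, with 3 counts over the group as the floor. Rgn had 2 counts on HFD and 7.22 ± 10.4 CPM on ND. The depot weighed 1.38 ± 0.123 on ND and 1.35 ± 0.186 on HFD, a difference within the spread between mice (exact permutation p = 0.9).

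**Figure D4:**
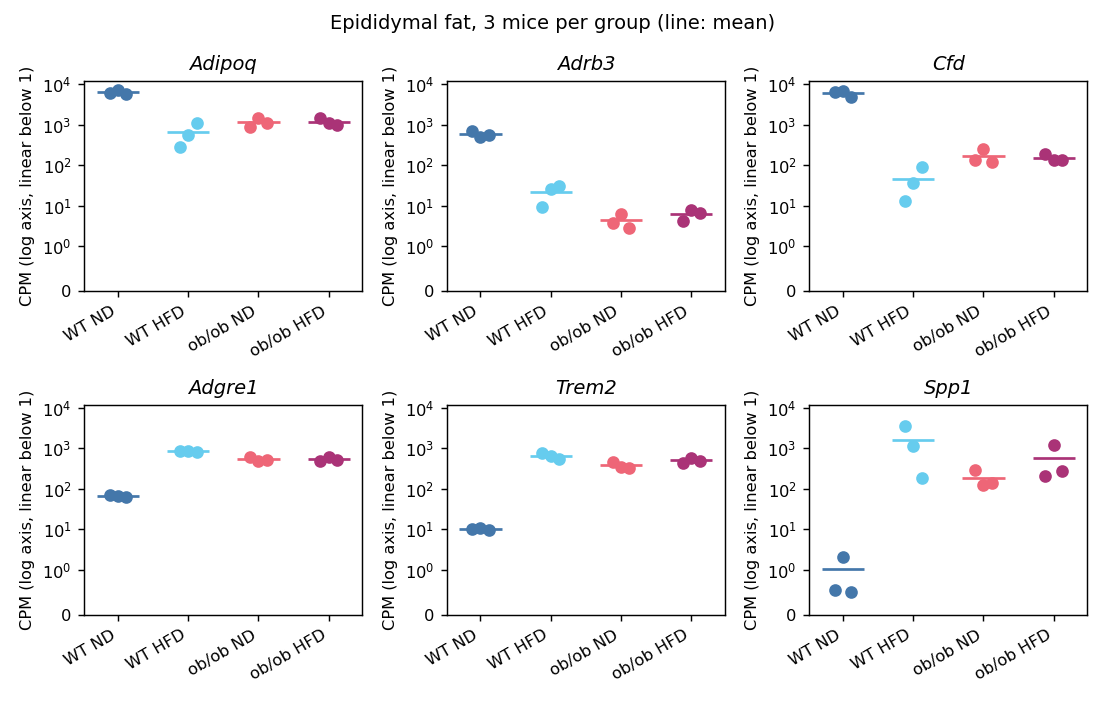
CPM of 6 transcripts in each of the 12 epididymal fat libraries, on an axis that is logarithmic above 1 CPM and linear below; points are mice and lines are group means. Adipoq averages 6330 CPM in WT mice on ND and 656 CPM on HFD, and Spp1 1.06 and 1656 CPM.

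In the liver of WT mice 2890 of 13246 genes differed on HFD (1583 higher and 1307 lower), 1819 without the first mouse on ND. Interferon response genes rose, 19 of 21 members rose, 0 fell and 2 did not pass (19 and 0 adjusted over the list alone, adjusted p = 8.07e-21 by camera, adjusted p = 0.388 with an estimated correlation). Rsad2 stood at 2.05 ± 0.19 and Ifit3 at 2.51 ± 0.24. Matrix genes rose, 18 of 27 members rose, 0 fell and 9 did not pass (22 and 1 adjusted over the list alone, adjusted p = 1.36e-12 by camera, adjusted p = 0.414 with an estimated correlation). Col4a1 stood at 1.44 ± 0.16. In the cytokine list 10 of 14 members rose, 1 fell and 3 did not pass (11 and 1 adjusted over the list alone, adjusted p = 3.69e-10 by camera, adjusted p = 0.388 with an estimated correlation). Examples were Lcn2 (5.62 ± 0.46) and the chemokine Cxcl10 (3.33 ± 0.37). Lipid droplet genes gave 7 rises among 16 (7 adjusted over the list alone, adjusted p = 1.3e-05 by camera, adjusted p = 0.404 with an estimated correlation). Mogat1 stood at 2.57 ± 0.26 and Cidec at 2.28 ± 0.24. For cholesterol synthesis and uptake 0 of 22 members rose, 13 fell and 9 did not pass (0 and 17 adjusted over the list alone, adjusted p = 5.35e-09 by camera, adjusted p = 0.503 with an estimated correlation). The demethylase Cyp51 stood at -2.26 ± 0.36. Of the male-biased genes 0 of 19 members rose, 9 fell and 10 did not pass (1 and 10 adjusted over the list alone, adjusted p = 1.43e-06 by camera, adjusted p = 0.49 with an estimated correlation). Elovl3 stood at -2.46 ± 0.30. In the clock list 10 of 19 members rose, 3 fell and 6 did not pass (10 and 3 adjusted over the list alone, adjusted p = 0.00219 by camera, adjusted p = 0.404 with an estimated correlation). Ciart stood at 3.12 ± 0.24, Per2 at 1.75 ± 0.20 and Clock at -0.56 ± 0.08. Cyp2b13 rose from 2 counts on ND to 28.6 ± 33 CPM and Ephb2 from 1 count to 4.87 ± 3.58 CPM. The retinoic acid hydroxylase Cyp26a1 (-4.07 ± 0.56), Cyp2c69 (-4.42 ± 0.55) and the signalling protein Smad9 (-3.62 ± 0.31) fell.

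In the aorta of WT mice 621 genes differed on HFD (315 higher and 306 lower). Contractile smooth muscle genes fell where they passed, 0 of 14 members rose, 5 fell and 9 did not pass (1 and 10 adjusted over the list alone, adjusted p = 1.22e-06 by camera, adjusted p = 0.47 with an estimated correlation). Tagln stood at -1.49 ± 0.25 and Cnn1 at -1.49 ± 0.27. For fatty acid oxidation 4 of 24 members rose, 0 fell and 20 did not pass (12 and 1 adjusted over the list alone, adjusted p = 1.43e-06 by camera, adjusted p = 0.47 with an estimated correlation). The hormone gene Fgf21 stood at 2.78 ± 0.57. Tph2 rose (4.68 ± 0.57), Rspo4 went from 1 count to 8.53 ± 0.789 CPM, and Slc5a7 from 0 counts to 1.07 ± 0.186 CPM, at least 14.9-fold higher. The xenobiotic enzyme Cyp1a1 (ENSMUSG00000032315; chromosome 9, 57687928 to 57703824) went from 3.90 ± 0.934 CPM to 1 count, Cyp2e1 had -2.93 ± 0.26 and the natriuretic peptide Nppa -4.52 ± 1.13. Nppa is made by heart muscle cells, and the heart myosin Myh6 was 49.5 ± 47.2 CPM in aorta of WT mice on ND and 11.7 ± 20.0 CPM on HFD. Nppa lost its call without any 1 of 6 libraries (adjusted p up to 0.162 by edgeR) and by DESeq2 (adjusted p = 0.283), Fgf21 without any of 4 (up to 0.0648), and Tagln and Cnn1 without WT mouse 1 on HFD (0.0522 and 0.0642). The aorta count depended on single mice, with 1494 without WT mouse 1 on ND, 355 and 302 without mice 2 and 3, and 169, 355 and 214 without WT mouse 1, 2 or 3 on HFD. DESeq2 called 1176.

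In the heart of WT mice 35 genes differed on HFD (15 higher and 20 lower), and 78 by DESeq2. Cyp1a1 fell from 1.57 ± 0.347 CPM to 1 count, the transaminase Abat had -2.28 ± 0.26 and Chac1, which degrades glutathione, -1.59 ± 0.25. Upward went the mast cell protease Mcpt4 (1.93 ± 0.28), endothelin-3, Edn3 (1.46 ± 0.29), and Olfr1396 (1.34 ± 0.21). In the interferon list 2 of 21 members rose, 0 fell and 19 did not pass (16 and 0 adjusted over the list alone, adjusted p = 7.87e-21 by camera, adjusted p = 0.274 with an estimated correlation). Irf7 stood at 0.87 ± 0.13. The heart count was 6, 5 and 20 without WT mouse 1, 2 or 3 on HFD, 7 and 5 without mouse 1 or 3 on ND, and 20 without ob/ob mouse 1 on ND. Most of these calls also rested on single libraries: Cyp1a1 lost its call without any 1 of 10 (adjusted p up to 0.188 by edgeR), Edn3 without any of 9 (0.179), Olfr1396 and Chac1 without any of 4 (0.0988 and 0.0777), Irf7 without any of 3 (0.0628) and Mcpt4 without WT mouse 1 on HFD or 3 on ND (up to 0.069). In hippocampus, hypothalamus and skeletal muscle edgeR called 0 genes for HFD in WT mice. At an unadjusted p under 0.05 there were 328, 669 and 2796 genes, and DESeq2 called 0, 1 and 838. Without the filter on low counts edgeR called 0, 173 and 357. The muscle count was 1799 without the first ob/ob mouse on HFD and 1 without the third WT mouse on HFD.

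In ob/ob liver some lipid synthesis genes were lower on HFD. There 121 genes were called (50 higher and 71 lower). In the fatty acid synthesis list 0 of 17 members rose, 9 fell and 8 did not pass (0 and 14 adjusted over the list alone), with adjusted p = 2.31e-42 by camera. This was the only one of the 156 list tests of this comparison to hold with an estimated correlation (adjusted p = 0.0134 with an estimated correlation). Scd1, the main desaturase of liver, had -1.52 ± 0.15, the elongase Elovl6 -1.86 ± 0.18, ATP citrate lyase, Acly, -1.60 ± 0.19 and the acetyl-CoA synthetase Acss2 -1.41 ± 0.13. For cholesterol synthesis and uptake 0 of 22 members rose, 1 fell and 21 did not pass (0 and 13 adjusted over the list alone, adjusted p = 5.82e-17 by camera, adjusted p = 0.4 with an estimated correlation). Pmvk stood at -0.99 ± 0.18. The amino acid transporter subunit Slc3a1 (2.01 ± 0.23) and Lcn2 (1.96 ± 0.32) rose, and Cyp2c69 (-3.38 ± 0.57), the phosphate transporter Slc34a2 (-3.01 ± 0.58) and the adenylyl cyclase Adcy1 (-2.66 ± 0.43) fell. Pmvk lost its call without any 1 of 4 libraries (adjusted p up to 0.086 by edgeR), Lcn2, Cyp2c69 and Slc34a2 without any of 3 (0.0779, 0.0591 and 0.123) and Adcy1 without ob/ob mouse 1 on ND (0.0569). The liver count was 38, 45 and 37 without ob/ob mouse 1, 2 or 3 on ND and 54 without mouse 2 on HFD. DESeq2 called 298.

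In heart 3 genes differed on HFD in ob/ob mice. They were Cyp1a1, from 6.21 ± 4.44 CPM to 2 counts, potassium channel subunit Kcnip2 (-0.70 ± 0.08) and guanine deaminase, Gda (0.75 ± 0.12). The heart count was 11 and 6 without ob/ob mouse 2 or 3 on ND, 5 without mouse 1 on HFD, and 6 and 10 without WT mouse 1 or 2 on ND. Gda lost its call without any 1 of 4 libraries (adjusted p up to 0.191 by edgeR). DESeq2 called 28. edgeR called 0 genes in aorta, epididymal fat, hippocampus, hypothalamus and skeletal muscle. At an unadjusted p under 0.05 there were, in that order, 594, 848, 460, 547 and 137 genes, and DESeq2 called 14, 16, 2, 1 and 1. Without the filter on low counts edgeR called 68, 0, 1, 39 and 0. Without ob/ob mouse 1 on HFD edgeR called 2 genes in aorta, and without ob/ob mouse 2 on ND 1 in hippocampus.

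The effect of HFD differed between the genotypes in epididymal fat, where 6285 of 15676 genes had an interaction (3045 with a more positive and 3240 with a more negative diet effect in ob/ob mice). Of 100 splits of the mice within genotype, 9 gave as many or more, the real one among them, and all 9 kept the WT mice on their own diets. Of the macrophage markers, 21 of 24 had a lower diet effect in ob/ob mice (21 adjusted over the list alone, adjusted p = 4.75e-26 by camera, adjusted p = 0.424 with an estimated correlation). An example was Trem2 (-5.58 ± 0.25). White adipocyte genes went the other way, 17 of 20 with a higher diet effect (17 adjusted over the list alone, adjusted p = 2.99e-10 by camera, adjusted p = 0.548 with an estimated correlation). Adrb3 stood at 5.28 ± 0.60 and Cfd at 6.86 ± 0.81. In the macrophage gene Spp1 the diet step was 1.06 ± 0.913 to 1656 ± 1800 CPM in WT mice and 187 ± 97.7 to 569.7 ± 574 CPM in ob/ob mice. In Hmga2 and St18, at 0 counts in WT fat on ND, the ob/ob groups held 14.8 ± 6.19 and 14.9 ± 1.07 CPM and 6.40 ± 1.52 and 6.71 ± 1.05 CPM.

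In liver 817 genes had an interaction (292 and 525), 487 without WT mouse 1 on ND and 494 without WT mouse 1 on HFD. Interferon genes had a lower diet effect in ob/ob mice, 12 of 21 (17 adjusted over the list alone, adjusted p = 3.04e-19 by camera, adjusted p = 0.424 with an estimated correlation). Rsad2 stood at -2.43 ± 0.26. Lipid droplet genes did so too, 6 of 16 (7 adjusted over the list alone, adjusted p = 1.47e-09 by camera, adjusted p = 0.424 with an estimated correlation). Mogat1 stood at -2.87 ± 0.34. Cyp4a12b had 5.45 ± 1.002, a near copy of Cyp4a12a and therefore uncertain. Pitx3 went from 7.02 ± 3.24 to 0.774 ± 0.177 CPM in WT mice and held 3 counts in ob/ob mice on ND. In aorta 63 genes had an interaction, among them Lep (-4.01 ± 0.42), Cyp2e1 (3.30 ± 0.36) and resistin, Retn (2.61 ± 0.36). The aorta samples held fat, as given above. The aorta count ran from 24 without WT mouse 1 on HFD to 326 without WT mouse 1 on ND, and DESeq2 called 318. It was 29 and 29 without WT mouse 2 or 3 on HFD, 40 without WT mouse 3 on ND, 25 and 35 without ob/ob mouse 1 or 3 on ND and 38 without ob/ob mouse 3 on HFD. By edgeR 0 genes had an interaction in heart, hippocampus, hypothalamus and skeletal muscle, with 1087, 368, 602 and 1840 at an unadjusted p under 0.05 and 2, 0, 2 and 66 by DESeq2. Without the filter on low counts edgeR gave 177, 0, 111 and 1. Leaving out ob/ob mouse 1 gave 4 in muscle (the mouse on HFD) and 1 in heart (the mouse on ND).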

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

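The interaction splits were chosen after the interaction counts were seen; the splits for genotype, diet and shared genes were set before. The response to HFD differed between WT and ob/ob mice, by the interaction term of edgeR, for 6285 genes in epididymal fat, 817 in liver and 63 in aorta, and 73 list tests passed with the preset correlation and 0 with an estimated one. In epididymal fat the adipokine gene Cfd (interaction 6.86 ± 0.81, adjusted p = 0.000124), St18 (adjusted p = 9.51e-06), Hmga2 (adjusted p = 0.00106) and Rgn (adjusted p = 0.0384) passed the diet test in WT mice and not in ob/ob mice, where their log2 fold changes were -0.14 ± 0.52, 0.07 ± 0.22, 0.02 ± 0.51 and -0.09 ± 1.35. In liver the genes were Pitx3 (adjusted p = 0.00312), Cyp4a12b (0.00719), Cyp2b13 (0.0142) and Sprr1a (0.0254). Cyp2b13 and Cyp4a12b have near-identical copies and are uncertain. In aorta they were Cyp2e1 (adjusted p = 0.00111), Retn (0.00842), Rspo4 (0.0119) and Slc5a7 (0.0382). Rgn and Slc5a7 lost the call without any 1 of 8 libraries (adjusted p up to 0.13 and 0.114) and Sprr1a without any of 5 (up to 0.0627).

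Splitting the mice of each genotype into other groups of 3 cannot decide on chance for the interaction counts. In epididymal fat 9 of the 100 splits drawn gave as many genes (highest other 8007), in liver 7 (2378) and in aorta 8 (738). The real split is 1 of each of these numbers. All of them kept the WT mice on their own diets, as 12 of the 100 splits did, and so kept the WT diet effect. With the WT diets mixed the highest count was 0 in epididymal fat, 1 in liver and 0 in aorta. In heart, hippocampus, hypothalamus and skeletal muscle the real count was 0, which all 100 splits reached, with highest others of 62, 2320, 9 and 3349. The highest split in muscle kept the WT mice on their own diets (highest with them mixed 1), while in hippocampus a split with them mixed gave 2320. For the 73 list tests, 10 of 100 splits gave as many (highest other 86).

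Chance was excluded for genotype counts except in muscle. Only the real split gave as many in aorta (1 of 100; 5844 against a highest other of 1673), heart (4119 against 1043), hippocampus (2272 against 126), hypothalamus (2565 against 182) and liver (5664 against 2842). In epididymal fat 2 of 100 did (5621 against 6285), the other being the split with genotype exchanged on 1 diet, which is the interaction itself. In skeletal muscle 3 of 100 did (7506 against 9169). The 1671 genes shared by at least 4 tissues had a highest other of 32, and chance was excluded (1 of 100). The 71 list tests called for genotype did not meet that limit, since 20 of 100 splits gave as many (highest other 87).

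The diet contrasts have 10 splits each, too few for a share under 0.05. For HFD in WT mice the real count and the highest other were 621 and 0 in aorta, 9227 and 0 in epididymal fat, 35 and 5 in heart and 2890 and 0 in liver. They were 0 and 1 in hippocampus and 0 and 0 in hypothalamus and skeletal muscle, and 75 and 76 for the list tests. For HFD in ob/ob mice they were 121 and 2 in liver, 3 and 6 in heart, 0 and 1 in epididymal fat, 0 and 0 in the other 4 tissues, and 66 and 76 for the list tests.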

How the results depend on the processing

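The covariates, both exclusions of 2 muscle libraries and genotype on each diet alone were chosen after the data were seen; the other alternatives were planned. Of the 220 called values of genes named or taken by the naming rule, 198 kept their call without each library in turn. None of the 220 changed direction under any alternative run on them. Genotype on each diet alone was run on counts, lists, Lep and Lepr. There called list members changed direction on HFD in 5 tissues, the most in epididymal fat (56 of 180) and liver (18 of 259). On ND they did in 3, epididymal fat (11), liver (7) and heart (1). DESeq2 ended 1 call of a named gene, Nppa in aorta, and gave no adjusted p for 3 other values. Values that had not passed could change sign without 1 library: log2 fold changes of HFD in ob/ob fat ran over -0.33 to 0.26 for Cfd, -0.21 to 0.40 for Hmga2, -1.33 to 0.64 for Rgn and -0.11 to 0.22 for St18, and of Lep in liver for genotype over -0.58 to 2.76. DESeq2 size factors in edgeR left all 33 counts within 1.5 times. All 72 phenotype tests on ranks and 64 on log2 stood, but diet within a genotype cannot pass. Counts of called genes moved over 1.5 times as follows, and the cause was not tested. With DESeq2, HFD in WT mice gave 1176 in aorta, 78 in heart, 1 in hypothalamus and 838 in muscle, HFD in ob/ob mice 14 in aorta, 16 in epididymal fat, 28 in heart, 2 in hippocampus, 1 in hypothalamus, 298 in liver and 1 in muscle, and the interaction 318 in aorta, 2 in heart, 2 in hypothalamus and 66 in muscle. With no filter on low counts, HFD in WT mice gave 1702 in aorta, 343 in heart, 173 in hypothalamus and 357 in muscle, HFD in ob/ob mice 68 in aorta, 360 in heart, 1 in hippocampus, 39 in hypothalamus and 976 in liver, and the interaction 760 in aorta, 177 in heart, 111 in hypothalamus, 1496 in liver and 1 in muscle. With the adipocyte score as a covariate, muscle gave 202 for genotype and 1 for HFD in WT mice. Without the first WT mouse on ND and the first ob/ob mouse on HFD, picked by eye, muscle gave 9999 for genotype, 865 for HFD in WT mice and 1 for the interaction. Without the 2 muscle libraries farthest from the median library, the first WT mouse on ND and the second ob/ob mouse on HFD, it gave 5654, 0 and 0, so the count for HFD in WT mice depends on which libraries are left out. Genotype on ND alone gave 1742 in heart, 569 in hippocampus and 877 in hypothalamus. On HFD alone it gave 2389 in aorta, 2752 in epididymal fat, 2349 in heart, 255 in hippocampus, 353 in hypothalamus, 2445 in liver and 3 in muscle. The brown adipocyte score gave 189 for the interaction in aorta. With an estimated correlation, 0, 0, 1 and 0 list tests passed for genotype, HFD in WT, HFD in ob/ob and the interaction, and 635 genes were shared by at least 5 tissues.

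Leaving out 1 library in turn, the counts ran over 1407 to 2409 in hippocampus and 1601 to 4511 in hypothalamus for genotype. For HFD in WT mice the ranges were 169 to 1494 in aorta, 5 to 36 in heart, 1819 to 3190 in liver and 0 to 1799 in muscle. For HFD in ob/ob mice they were 0 to 2 in aorta, 2 to 11 in heart, 0 to 1 in hippocampus and 37 to 168 in liver, and for the interaction 24 to 326 in aorta, 0 to 1 in heart, 487 to 908 in liver and 0 to 4 in muscle. Without 1 mouse in turn, the phenotype differences whose call was lost ran over 78.08 to 117.8 mg/dL for total cholesterol and -72.17 to -54.42 for fasting glucose by genotype. Those that gained a call ran over 7.333 to 142.3 uEq/L for free fatty acids and 0.23 to 0.5175 for free water by genotype, and over 9.375 to 11.77 for body weight, 7.623 to 9.474 for body fat, -0.03325 to -0.014 for brain weight and 1.063 to 1.41 for retroperitoneal fat by diet.

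The mouse numbers do not pair the samples: mice of different groups are different animals, and same-numbered libraries had deviations with a median correlation between -0.082 and 0.08 depending on tissue, with 1 to 7 of 12 libraries correlating best with their own number. With the replicate block, HFD in ob/ob hearts gave 9 genes and the genotype count in hippocampus was 1582. It left the other 32 counts within 1.5 times, the hippocampus count included, and no call of a named gene was lost with it. Depth limits the low genes: with 10499528 counts in the shallowest library, a gene at 1 CPM has about 10 counts there, so values of genes with few counts are given as levels or lower bounds.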

Other observations

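The tests of sample order, muscle fibre share and body temperature, and all values of genes outside the naming rule, were chosen after the results were seen; those of the Lep segment, clustered loci, fat in the muscle samples and time of day were set before their results were seen, on patterns found in these data. Genes of cell division were higher in liver and skeletal muscle of ob/ob mice too, as the mean over both diets; on HFD alone 0 of them passed in either tissue. In skeletal muscle 17 of 20 members rose, 1 fell and 2 did not pass (18 and 1 adjusted over the list alone, adjusted p = 0.000138 by camera, adjusted p = 0.637 with an estimated correlation). The checkpoint kinase Bub1b stood at 1.59 ± 0.27. In liver 14 of 20 members rose, 0 fell and 6 did not pass (16 and 0 adjusted over the list alone, adjusted p = 0.0011 by camera, adjusted p = 0.646 with an estimated correlation). The cell cycle kinase Cdk1 stood at 1.27 ± 0.17. Heat shock genes mostly fell where they passed in the other peripheral tissues. In heart 1 of 15 members rose, 10 fell and 4 did not pass (1 and 14 adjusted over the list alone, adjusted p = 4.14e-07 by camera, adjusted p = 0.374 with an estimated correlation), in aorta 1 of 15 members rose, 10 fell and 4 did not pass (1 and 12 adjusted over the list alone, adjusted p = 0.000227 by camera, adjusted p = 0.627 with an estimated correlation), and in epididymal fat 2 of 15 members rose, 8 fell and 5 did not pass (2 and 8 adjusted over the list alone, adjusted p = 0.0016 by camera, adjusted p = 0.588 with an estimated correlation). The inducible chaperone Hspa1a had -1.85 ± 0.22 in aorta and -1.53 ± 0.20 in epididymal fat, and it has a near-identical copy, Hspa1b, so its own value is uncertain. Lcn2 was higher in aorta (1.55 ± 0.23), epididymal fat (2.60 ± 0.19), liver (2.96 ± 0.28) and hypothalamus (2.11 ± 0.45).

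Some matrix genes were higher in the hypothalamus of ob/ob mice, where 7 of 26 members rose, 0 fell and 19 did not pass (11 and 0 adjusted over the list alone, adjusted p = 6.28e-05 by camera, adjusted p = 0.324 with an estimated correlation). In hippocampus the glucocorticoid-responsive list was higher where it passed, 6 of 20 members rose, 0 fell and 14 did not pass (8 and 0 adjusted over the list alone, adjusted p = 0.00132 by camera, adjusted p = 0.42 with an estimated correlation). In the fatty acid synthesis list of the aorta 8 of 16 members rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone, adjusted p = 0.0011 by camera, adjusted p = 0.629 with an estimated correlation), Scd2 at 2.49 ± 0.15 and Scd1 at 1.64 ± 0.20 among them. In skeletal muscle 11 of 16 members rose, 3 fell and 2 did not pass (11 and 3 adjusted over the list alone, adjusted p = 0.00549 by camera, adjusted p = 0.627 with an estimated correlation), Elovl6 at 2.15 ± 0.32 and Acaca, the first enzyme of the pathway, at 2.19 ± 0.33 among them. The transhydrogenase Nnt was higher in 6 tissues, from 0.64 ± 0.07 in epididymal fat to 1.998 ± 0.09 in liver. In skeletal muscle (0.88 ± 0.44, adjusted p = 0.116 by edgeR) it passed only without WT mouse 3 (1.26) or ob/ob mouse 2 (1.10) on HFD. With the adipocyte score as a covariate, Bub1b (log2 fold change 1.44 ± 0.37, adjusted p = 0.0698) and Elovl6 (1.45 ± 0.41, 0.0854) lost their calls in muscle by edgeR.

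The 74 genes called the same way in all 7 tissues may reflect leptin loss, or differences that came with the animals. For a chromosome segment carried along with the Lep mutation, 0 percent of them lay within 20 Mb of Lep, where 1.1 percent of the tested genes lie. So they do not sit in a segment of that size. With few tested genes there, 0 percent differs little from that share. A longer segment, or effects of a segment on genes elsewhere, were not tested. Strain differences at clustered loci elsewhere stay open, as no strain is named for the WT mice. Of these genes 5 pairs lay within 1 Mb, against a mean of 4.48 in random draws, 45.41 percent of which had as many. Single loci, such as Wdfy1 and Nnt, were not tested. Sample numbers run group by group in 7 of 7 tissues. So handling in that order cannot be told apart from genotype or diet, here or in any count above. Genotype itself was not tested apart from these.

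Adipocyte transcripts in the muscle samples of ob/ob mice are consistent with fat tissue inside the samples, where Adipoq, among its abundant transcripts, averaged 137 ± 140.0 CPM in WT and 1305 ± 317 CPM in ob/ob mice on ND, and 1043 ± 303 and 1323 ± 910.0 CPM on HFD. The groups on HFD overlap, and the tests below take the mean over both diets. Of 79 genes abundant in epididymal fat (at least 50 CPM) and near absent from WT muscle on ND (at most 5 CPM), 96.2 percent had a log2 fold change above 0, against 63.3 percent of 5191 other genes that were near absent. Their medians were 1.80 and 0.36. A lower share of muscle fibres alone would raise all other cell types alike. The endothelial median was 0.35 (quartiles 0.20 and 0.59) and the adipocyte median 1.63 (0.82 and 2.06), a difference of -1.28. This argues against it for these lists only and does not exclude it. Called macrophage markers had a median of 2.9 on ND and 0.83 on HFD, near the 3.18 and 0.77 of called white adipocyte genes. Whether such fat lay between the fibres in life or was taken along at dissection was not tested.

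In ob/ob mice more heat shock genes were lower than higher in all 7 tissues, and in heart and hypothalamus 13 clock genes each were higher. Another time of day at collection may move clock genes, and would move Arntl and its partners against the Dbp and Per group. These groups went in opposite directions and lay over 0.5 apart in 3 tissues, heart (-0.31 against 0.57), aorta (-0.09 against 0.44) and, with both signs exchanged, muscle (0.39 against -0.31), and under 0.5 apart in the other 4, so this stays open. A lower body temperature of ob/ob mice is a candidate explanation of the heat shock genes: in 7 of the 7 tissues Cirbp and Rbm3, which cold induces, were higher. Body temperature was not measured here, so it cannot be told apart from other effects of genotype.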
